A study of Rattus norvegicus with 20 samples.

How the data were processed

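RNA was sequenced from the livers of 20 male rats in 4 groups of 5, and the group and replicate number of each library were taken from the sample labels. Per the labels, total RNA was extracted with Trizol, treated with DNase I, made into libraries with a TruSeq kit and sequenced in pairs, of which only read 1 was analysed by the authors. Doses were taken from the labels, namely CMC-Na at 0.5%, hydrocortisone at 25 mg/kg and BGZ_L powder at 0.9 g/kg. The aligner and the counting tool are not given in the sources used here. The authors' processing notes list the builds GRCm38, mm10 and GRCm39, which are mouse builds, whereas every gene identifier in the table is a rat Ensembl identifier, so the genome build behind the values is not known.

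The deposited table is named as raw counts, but its values were read as TPM, a length-scaled unit. This was inferred from the values, which have 2 decimals and sum to 914241 to 983958 in every library. These features alone do not show that the values are length-scaled. How the authors computed these values is not stated in the sources used here. The count test planned from the table's name could not be applied to TPM, so limma on log2 TPM replaced it. The depth per library is unknown, since TPM keeps no totals, and no confidence interval or detection limit that needs a depth was computed. Fold changes on a log2 scale with an added constant understate differences of genes with low values.

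Values for 32883 genes and 20 libraries were read, with no library left out. Of the gene identifiers, 33 had no symbol and held at most 0.0111% of a library, and 2867 shared a symbol with another identifier. A symbol with several identifiers was read from the one with the highest mean. Among the genes were 13 mitochondrially encoded genes and 328 ribosomal RNA genes. No 2 libraries had identical values, and the highest correlation between libraries was 0.964.

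TPM values were scaled between libraries by a trimmed mean of log ratios, unweighted, with 30% of ratios and 5% of levels trimmed at each end. Genes with a scaled TPM of at least 0.5 in at least 5 libraries were tested, 11867 in all, as log2 of the scaled TPM plus 0.5. The 4 group means were fitted in 1 limma model with a trended and robust prior and 16 residual degrees of freedom. Each comparison was a contrast of that model, two-sided, with Benjamini-Hochberg adjustment over the 11867 genes and a threshold of 0.05. The comparisons were KYDS against CON, KYDS+BGZ_L against KYDS, BGZ_L against CON, KYDS+BGZ_L against CON, the interaction of BGZ_L and hydrocortisone, and KYDS+BGZ_L against BGZ_L. Tools were R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with matplotlib 3.10.9 for the figures.

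The groups, the first 5 contrasts, the gene lists, the naming rule, the threshold and the first set of alternatives were fixed before the data were examined. The scaling, the filter level and the added constant were settled after counts under several scalings had been looked at. KYDS+BGZ_L against BGZ_L was added after the data were seen. Gene lists, 36 in number, were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 36 lists within a comparison, and again with an estimated correlation and with fry. Members of each list were also adjusted over the list alone. Values of single libraries, such as shares of TPM, were compared by exact permutation tests of 5 against 5 libraries (smallest possible p = 0.00794). PC1 and correlations over 20 libraries were tested by permutation with 100000 resamples.

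Genes were named by a rule. It took the 6 highest and 6 lowest fold changes among genes that passed, had a mean log2 value of at least 1, a gene symbol other than a provisional name, and groups that did not overlap. Where none passed, it took the 3 genes with the smallest unadjusted p in each direction. It added 2 members of each of the 6 lists with the smallest camera p, 4 genes for the interaction and a set of genes chosen for liver and glucocorticoid biology. Clone-style names and shared symbols were read as provisional names after the data were seen. Some genes that the rule took are not reported here and were not replaced. Any other gene is said to have been chosen after its values were seen.

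The replicate numbers of the labels were checked as a possible pairing of rats across groups. Of 30 correlations between libraries with the same number in 2 groups, 7 were above 0.1 (-0.458 to 0.335), and 2 of 20 libraries matched their own number best, so no block was used, and the block was run as an alternative. The method was tested on simulated data with 11700 genes and 5 libraries per group. For KYDS against CON, 25 of 100 genes changed by 1 log2 and 80 of 100 genes changed by 2 log2 were called. Also called were 11 unchanged genes, a larger share of these calls than the adjustment threshold aims at. In another limma contrast 0 unchanged genes were called. The simulation was no test of libraries whose mitochondrial share of TPM differs widely, as it does here. These counts therefore give no error rate for the real calls.

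The first set of alternatives was median-ratio scaling, no filter, a stricter filter at a TPM of 1, only the groups of each comparison, the replicate block, leaving out the 10 most abundant genes and leaving out each library in turn. Alternatives chosen after seeing the data were an added constant of 0.1 or 1, no scaling, TPM recomputed without mitochondrial and ribosomal RNA genes, array weights, the log2 ratio of nuclear to mitochondrial TPM as a covariate, and leaving out CON 2 and BGZ_L 3, which had the lowest scaling factors.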

Results

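RNA was measured in the livers of 20 male rats, with 1 sequencing library per rat and 5 rats in each of 4 groups. CON rats received the vehicle, 0.5% CMC-Na. BGZ_L rats received BGZ_L powder at 0.9 g/kg, a preparation that the series title ties to Psoraleae Fructus. KYDS rats received hydrocortisone at 25 mg/kg, the glucocorticoid used to model kidney-yang deficiency syndrome, and KYDS+BGZ_L rats received both. Values were read as length-scaled transcript abundances (TPM) for 32883 rat genes, and they sum to 914241 to 983958 per library. TPM values keep no read totals, so the depth of each library is unknown and a value listed at 0 carries no upper limit. Values of single genes below are TPM after a scaling between libraries, as mean ± SD with n = 5. Fold changes are log2 values ± SE from 1 limma fit of 11867 genes in all 20 libraries, and adjusted p values are two-sided limma values corrected over those genes.

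The 13 mitochondrially encoded genes took most of the RNA signal in many livers, with lower means in the groups that received hydrocortisone. Their share of TPM was 75.1% ± 10.2 (SD, n = 5) in CON and 67.3% ± 17.3 in BGZ_L libraries. It was 42.4% ± 18.0 in KYDS and 48.9% ± 17.7 in KYDS+BGZ_L libraries. Single libraries ranged from 19.2% in KYDS 3 to 90.1% in CON 2. The difference between KYDS and CON had an exact permutation p of 0.0238 (two-sided), and 0.190 after adjustment over 16 library tests, and that between KYDS+BGZ_L and BGZ_L had 0.135, and 0.308 adjusted. Scaling factors were 0.774 ± 0.424 in CON and 1.72 ± 0.255 in KYDS (exact permutation p = 0.00794, the smallest that 5 against 5 libraries can give, and 0.127 adjusted), and their means were 0.785 in BGZ_L and 1.29 in KYDS+BGZ_L (exact permutation p = 0.0476, and 0.190 adjusted). The lowest factors were 0.231 in CON 2 and 0.345 in BGZ_L 3.

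Libraries with hydrocortisone also lay apart from the others on the first principal component of gene expression (PC1), which held 32.3% of the variance. The 10 libraries with hydrocortisone had a mean PC1 score of 41.4 ± 26.4 (SD) and the other 10 a mean of -41.4 ± 28.2, and no scores overlapped (permutation p = 3e-05). Within groups, PC1 followed the log2 ratio of nuclear to mitochondrial TPM. With both measures centred in each group, Pearson's r was 0.820 (permutation p = 1.3e-04) and Spearman's rho was 0.815 (permutation p = 1.9e-04) over 20 libraries. Without the 2 libraries farthest from the median ratio, r was 0.755. The labels give no batch, so no within-batch value can be had.

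**Figure D1:**
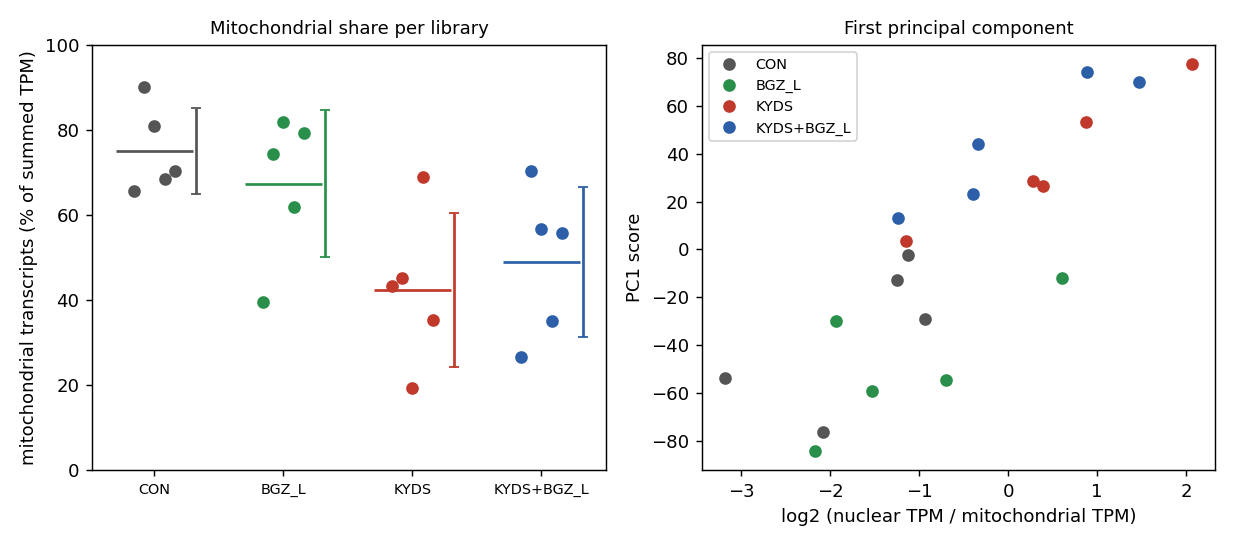
Mitochondrial share of TPM per library (percent, points are libraries, line and bar are mean and SD, n = 5), and PC1 score against the log2 ratio of nuclear to mitochondrial TPM. All 10 libraries with hydrocortisone have a PC1 score above those of the other 10, and libraries with more nuclear RNA lie higher on PC1.

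KYDS against CON asks what hydrocortisone alone did to the liver. Several genes of glucose production and handling were higher. The glucose-6-phosphatase gene G6pc went from 4.58 ± 10.1 TPM in CON to 87.7 ± 71.0 TPM in KYDS (log2 fold change 5.83 ± 0.98, adjusted p = 0.0026). The liver gene Gckr, a regulator of glucose use, went from 4.73 ± 3.77 to 46.4 ± 16.4 TPM (3.37 ± 0.40, adjusted p = 1.4e-04). Pyruvate carboxylase, Pc, rose by 1.57 ± 0.22 log2 (adjusted p = 6.6e-04), pyruvate kinase, Pklr, by 1.97 ± 0.34 (adjusted p = 0.0030) and the desaturase Scd by 3.15 ± 0.52 (adjusted p = 0.0022). Pc, Pklr and Scd were chosen after their values were seen.

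Ces2c, Tymp, Cyp8b1 and Tuba1c were also higher with hydrocortisone. The carboxylesterase Ces2c rose from 1.36 ± 1.38 to 43.7 ± 51.5 TPM (4.26 ± 0.58, adjusted p = 4.9e-04). Thymidine phosphorylase, Tymp, rose from 9.72 ± 5.13 to 117 ± 64.8 TPM (3.52 ± 0.47, adjusted p = 4.9e-04). The sterol 12-alpha-hydroxylase Cyp8b1 rose from 2.97 ± 1.63 to 20.05 ± 5.71 TPM (2.72 ± 0.54, adjusted p = 0.0096), and the tubulin gene Tuba1c rose by 3.12 ± 0.83 (adjusted p = 0.034). Among genes that the naming rule admits, the largest fall was in the secretoglobin Scgb1d4, from 1248 ± 826 to 89.8 ± 102 TPM (-5.62 ± 1.43, adjusted p = 0.030). Atl1 (-4.73), Arhgap40 (-4.22), Myh15 (-4.21), Cabp5 (-4.09) and Dnah7 (-3.79) also fell. None of these falls passed with the log2 ratio of nuclear to mitochondrial TPM as a covariate. Scgb1d4 was lower in BGZ_L 1 (307 TPM, mitochondrial share 39.6%) than in the other BGZ_L libraries (773 TPM or more). In CON it was lowest in CON 2 (483 TPM), where that share was highest (90.1%). Without hydrocortisone, Atl1 and Myh15 were at 2.50 and 2.29 TPM in BGZ_L 1 and at 4.07 and 3.53 TPM in BGZ_L 4. In the other BGZ_L libraries they were at 203 and 151 TPM or more. G6pc was listed at 0 in 3 of the 5 CON libraries and reached 22.6 TPM in CON 4, and its fold change depends on the constant added before the log.

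**Figure D2:**
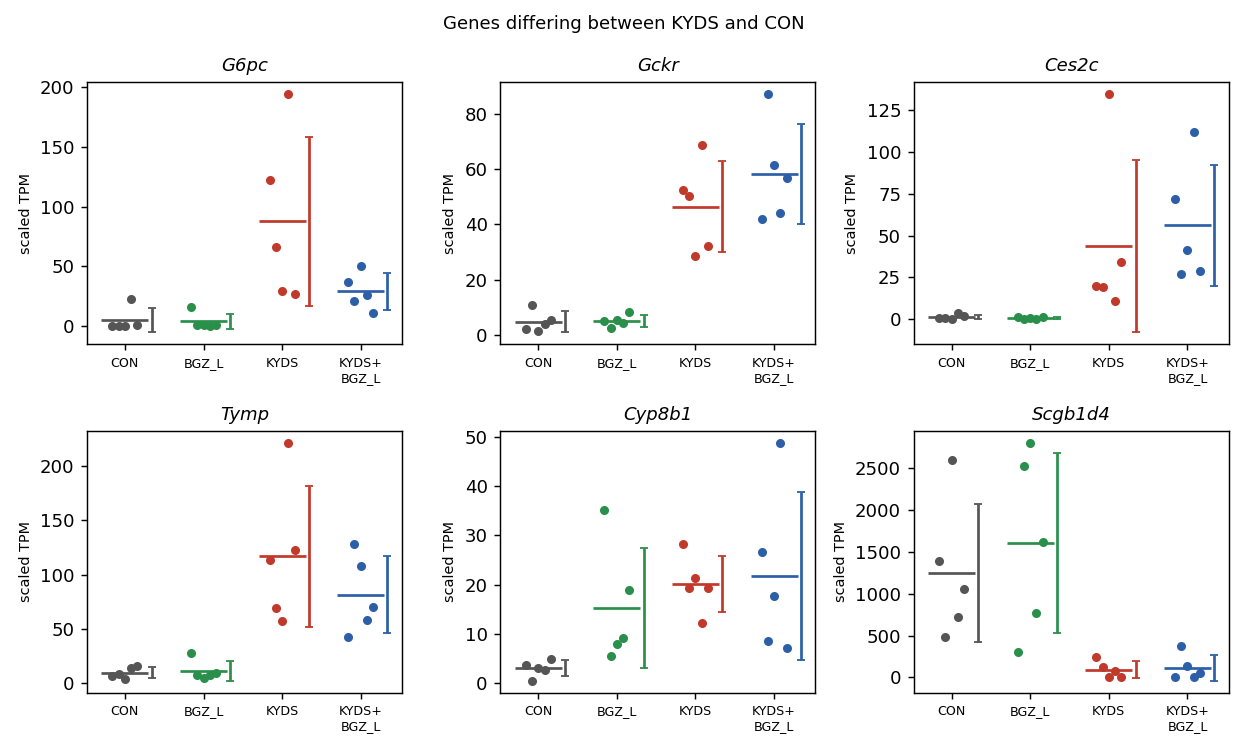
Scaled TPM per library (y axis, linear) of G6pc, Gckr, Ces2c, Tymp, Cyp8b1 and Scgb1d4 in the 4 groups (points are libraries, line is the mean, bar is the SD, n = 5). G6pc, Gckr, Ces2c and Tymp have higher means, and Scgb1d4 has a lower mean, in both groups that received hydrocortisone than in CON.

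Classical glucocorticoid receptor targets moved apart. The phosphatase gene Dusp1 rose by 2.15 ± 0.42 log2 (adjusted p = 0.0086) and Errfi1 by 1.29 ± 0.36 (adjusted p = 0.040), while Nfkbia fell by 0.66 (adjusted p = 0.044), or rose by 0.63 without scaling (adjusted p = 0.286). Dusp1, Errfi1 and Nfkbia were chosen after their values were seen. Fkbp5 (-0.57, adjusted p = 0.171), Tsc22d3 (-0.59, adjusted p = 0.294) and Per1 (-0.48, adjusted p = 0.392) did not pass, and all 3 had the opposite sign without scaling. Tat (0.40, adjusted p = 0.387) and the receptor gene Nr3c1 (0.39, adjusted p = 0.361) did not pass either. Of the 22 tested members of this list, 2 rose, 1 fell and 19 did not pass, with the same 2 and 1 when adjusted over the list alone. The list as a whole was not called (camera adjusted p = 0.752).

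Genes of glucocorticoid activation and growth passed by less. Hsd11b1, which regenerates active glucocorticoid, rose by 1.25 ± 0.37 (adjusted p = 0.048), and Igf1 rose by 1.45 ± 0.42 (adjusted p = 0.047). Leaving out 1 library ended the Hsd11b1 call in 15 of 20 fits and the Igf1 call in 14 of 20, with a highest adjusted p of 0.123 for each without KYDS 3. Cyp2b1 (1.77, adjusted p = 0.119), Cyp1a2 (0.61, adjusted p = 0.552), Cyp2c11 (0.56, adjusted p = 0.545), Cpt1a (0.61, adjusted p = 0.381) and Cyp1a1 (-0.76, adjusted p = 0.506) did not pass. Cyp7a1 (-0.89, adjusted p = 0.417) and Fasn (-0.09, adjusted p = 0.928) did not pass and had the opposite sign without scaling. Cyp3a2 was not analysed here.

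Genes of metabolism, secreted liver proteins, interferon response and protein folding stress lay higher as groups in KYDS than in CON. Of 36 gene lists, 11 were called by camera, 10 higher and 1 lower, and none kept its call with an estimated correlation, while fry called 7. In gluconeogenesis, 3 of 14 genes rose and 11 did not pass (6 rose and 1 fell when adjusted over the list alone). Its camera adjusted p was 0.0097, with adjusted p = 0.466 with an estimated correlation. In glycolysis and lipogenesis, 5 of 16 rose, led by Scd and Pklr, and 11 did not pass (7 rose adjusted over the list alone, adjusted p = 0.0056 and 0.466 with an estimated correlation). In bile acid synthesis and transport, 5 of 22 rose and 17 did not pass, with Amacr at 1.46 ± 0.25 (8 rose adjusted over the list alone, adjusted p = 0.0063 and 0.466 with an estimated correlation). In fatty acid oxidation, 4 of 28 rose and 24 did not pass, with Plin2 at 1.24 ± 0.35 (6 rose adjusted over the list alone, adjusted p = 0.0056 and 0.466 with an estimated correlation).

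Among secreted proteins, the acute phase genes Orm1 and Fga rose by 2.25 ± 0.54 and 2.02 ± 0.54 log2. In that list 3 of 19 rose and 16 did not pass (6 rose adjusted over the list alone, adjusted p = 0.0056 and 0.505 with an estimated correlation). The hepatocyte genes Ttr and Tf rose by 2.39 ± 0.61 and 1.40 ± 0.40, the 2 of 9 members that passed, and 7 did not (7 rose adjusted over the list alone, adjusted p = 0.0020 and 0.466 with an estimated correlation). The interferon response genes Tap1 and Usp18 rose by 1.46 ± 0.27 and 1.44 ± 0.25. Of 24 members 4 rose and 20 did not pass (6 rose adjusted over the list alone, adjusted p = 0.0020 and 0.466 with an estimated correlation). The stress genes Sesn2 and Chac1 rose by 1.63 ± 0.39 and 1.07 ± 0.30. Of 21 endoplasmic reticulum stress genes 4 rose and 17 did not pass (8 rose adjusted over the list alone, adjusted p = 0.0020 and 0.466 with an estimated correlation). Immediate-early genes had 2 of 13 higher, 11 not passing and 3 higher when adjusted over the list alone (adjusted p = 0.024 and 0.466 with an estimated correlation). Male-biased liver genes had 1 of 10 higher, 9 not passing and 1 higher when adjusted over the list alone (adjusted p = 0.024 and 0.466 with an estimated correlation). The calls of fatty acid oxidation and male-biased genes were lost without KYDS 3 (adjusted p = 0.061 and 0.096 at the most) or CON 4, and that of immediate-early genes without CON 3 (adjusted p = 0.105 at the most), CON 5, KYDS 4 or KYDS 5. With the nuclear to mitochondrial ratio as a covariate 7 of the 11 list calls ended. These were gluconeogenesis (adjusted p = 0.091), bile acid synthesis and transport (0.104), fatty acid oxidation (0.279), endoplasmic reticulum stress (0.235), male-biased genes (0.572), hepatocyte genes (0.572, with a median that went from 1.30 to 0.067) and acute phase genes (0.975, which turned to -0.032). The covariate also gave 5 new calls, clock (adjusted p = 0.018), cholesterol synthesis (0.041) and MHC class II genes (0.018) lower and glycerophospholipid (0.041) and erythroid genes (0.0014) higher. Without scaling 5 ended, gluconeogenesis (0.070), bile acid synthesis and transport (0.101), male-biased genes (0.075), acute phase genes (0.070) and immediate-early genes (0.070).

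The called list that was lower was the mitochondrially encoded transcripts, whose share of TPM fell from 75.1% in CON to 42.4% in KYDS. Of 13 members 8 fell and 5 did not pass, with 12 lower when adjusted over the list alone (camera adjusted p = 5.1e-09 and 0.466 with an estimated correlation). Mt-nd4l fell by 2.60 ± 0.57 and Mt-atp8 by 2.54 ± 0.58 log2. Of 17 clock genes 2 fell, Per2 by 1.22 ± 0.30 (with a sign that turned to 0.05 without scaling) and Cry1 by 1.78 ± 0.47, both chosen after their values were seen, and 15 did not pass (camera adjusted p = 0.0891). For cell cycle and thyroid hormone response genes the medians (0.21 and 0.17) and means (0.02 and 0.02) were above 0 while the test pointed lower, with neither list called (adjusted p = 0.987 for each). The endothelial list differed in the same way, with a median of 0.18, a mean of 0.04 and a test that pointed lower (adjusted p = 0.987). For NRF2 targets the median was -0.01 and the mean 0.02 with a test that pointed higher (adjusted p = 0.987).

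In all, 744 genes passed between KYDS and CON, 386 higher and 358 lower, of which 629 changed at least 2-fold, and 2856 had an unadjusted p under 0.05. The split was 288 higher and 379 lower with median-ratio scaling, 5866 and 66 without scaling, and 92 and 37 when TPM was recomputed over nuclear genes. Without scaling the median of all genes was 1.03 log2 higher in KYDS, the shift that scaling removes. With 1 library left out there were 324 genes without CON 1, 249 without CON 2, 346 without CON 3, 399 without KYDS 1, 433 without KYDS 2, 226 without KYDS 3 and 226 without KYDS 5. It gave 1075 genes at the most, without CON 4. With the nuclear to mitochondrial ratio as a covariate 23 genes passed, 21 of them among the 744, and 257 passed without CON 2 and BGZ_L 3, the libraries with the lowest scaling factors. G6pc, Gckr, Ces2c, Tymp, Cyp8b1, Pc, Pklr, Scd, Dusp1, Amacr, Tap1, Usp18 and Mt-nd4l passed whichever library was left out. Of these, only Gckr, Ces2c and Tymp also passed with the nuclear to mitochondrial ratio as a covariate. Leaving out KYDS 3 ended the calls of Scgb1d4 (adjusted p = 0.090), Tuba1c (0.086), Atl1 (0.117), Myh15 (0.124), Arhgap40 (0.0502), Dnah7 (0.063), Ttr (0.086), Tf (0.123), Orm1 (0.066), Fga (0.097) and Mt-atp8 (0.053). Cabp5 (0.061 without KYDS 5), Sesn2 (0.056 without CON 3), Chac1 (0.103 without CON 2), Plin2 (0.096 without CON 2), Errfi1 (0.116 without CON 2), Nfkbia (0.111 without KYDS 5), Cry1 (0.094 without CON 2) and Per2 (0.074 without KYDS 3) also lost their calls. These values are the highest per gene, and the calls were lost in 1 (Arhgap40) to 13 (Myh15) of the 20 fits without 1 library (6 of 15 for Chac1).

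KYDS+BGZ_L against BGZ_L asks the same of hydrocortisone in rats that all received BGZ_L. Its group means come from other libraries than those of KYDS and CON, but the limma fit shares its estimate of spread over all 20 libraries. This comparison was added after the data were seen, and its genes were chosen after their values were seen. Ces2c (5.40 ± 0.58 log2, adjusted p = 2.2e-05), Gckr (3.41 ± 0.40, adjusted p = 4.4e-05), Tymp (2.95 ± 0.47, adjusted p = 1.0e-03), G6pc (3.83 ± 0.98, adjusted p = 0.013), Hsd11b1 (2.09 ± 0.37, adjusted p = 0.0020) and Igf1 (1.57 ± 0.42, adjusted p = 0.016) rose again. Scgb1d4 fell again, by 4.96 ± 1.43 (adjusted p = 0.023). Cyp8b1 did not pass here (0.47 ± 0.54, adjusted p = 0.587), and the difference between its 2 responses did not pass as an interaction (-2.25 ± 0.77, adjusted p = 0.999). The phenobarbital-type gene Cyp2b1 rose by 3.76 ± 0.68 (adjusted p = 0.0024) and the hormone gene Fgf21 by 2.42 ± 0.44 (adjusted p = 0.0024). The glucocorticoid targets Nfkbia (-1.32 ± 0.19, adjusted p = 4.3e-04) and Tsc22d3 (-1.43 ± 0.33, adjusted p = 0.0082) fell.

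Several clock genes fell in this comparison, with Dbp at -4.37 ± 0.38 (adjusted p = 1.5e-06), Per2 at -3.61 ± 0.30 (adjusted p = 8.9e-07) and Nr1d1 at -2.50 ± 0.30 (adjusted p = 4.5e-05), while Arntl rose by 1.77 ± 0.26 (adjusted p = 5.3e-04). Of 17 clock genes 2 rose, 9 fell and 6 did not pass, with 3 higher and 9 lower when adjusted over the list alone (camera adjusted p = 3.7e-04, with adjusted p = 0.150 with an estimated correlation). Of 36 lists 17 were called, 14 higher and 3 lower, 0 kept their call with an estimated correlation and 13 were called by fry. The acute phase genes had 10 of 19 higher, 2 lower and 7 not passing, with 11 higher and 2 lower adjusted over the list alone (adjusted p = 0.0016 and 0.514 with an estimated correlation).

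In KYDS+BGZ_L against BGZ_L 2059 genes passed, 1045 higher and 1014 lower, with 3832 at an unadjusted p under 0.05. Median-ratio scaling gave 942 higher and 1092 lower, no scaling 1809 and 233 with a median of all genes of 0.63 log2, and nuclear TPM 532 and 368. Without single libraries there were 1336 genes without BGZ_L 3, 1140 without KYDS+BGZ_L 1 and 1101 without KYDS+BGZ_L 4. The Scgb1d4 call was lost without KYDS+BGZ_L 4 (adjusted p = 0.076) and the Igf1 call without KYDS+BGZ_L 1 (adjusted p = 0.053). Of the 386 genes higher in KYDS than in CON, 230 were also called higher here, where 33.99 would be shared by chance, and of the 358 lower 263 were also called lower, with 30.6 by chance. These chance values assume independent calls, whereas both comparisons share the estimate of spread of each gene. Both also differ in mean mitochondrial share, 75.1% in CON and 42.4% in KYDS, and 67.3% in BGZ_L and 48.9% in KYDS+BGZ_L. A difference in RNA composition common to both could give shared calls, kept signs and a correlation as well. No gene was called in opposite directions, at limma adjusted p values in both comparisons, and 97.9% of the higher and 98.0% of the lower genes kept their sign. Of all tested genes 53.6% and 46.4% had these signs. Across all genes, which are not independent replicates, the fold changes had a correlation of 0.761.

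KYDS+BGZ_L against KYDS asks what BGZ_L added in rats that also received hydrocortisone. Several genes of the circadian clock were lower. The clock-controlled factor Dbp fell from 43.1 ± 20.04 TPM in KYDS to 3.16 ± 0.484 TPM in KYDS+BGZ_L (-3.37 ± 0.38 log2, adjusted p = 3.4e-04, n = 5 per group). Per2 fell from 5.66 ± 1.94 to 0.704 ± 0.226 TPM (-2.31 ± 0.30, adjusted p = 0.0014) and Nr1d1 from 6.22 ± 2.38 to 1.11 ± 0.484 TPM (-2.03 ± 0.30, adjusted p = 0.0041). Per3 fell by 2.45 ± 0.47 (adjusted p = 0.039).

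In the same comparison 3 aryl hydrocarbon receptor targets were higher. The cytochrome P450 gene Cyp1a1 rose from 0.532 ± 0.319 to 18.6 ± 15.5 TPM (3.75 ± 0.67 log2, adjusted p = 0.025) and Cyp1a2 from 54.0 ± 29.3 to 628 ± 558 TPM (3.14 ± 0.58, adjusted p = 0.032). The quinone reductase gene Nqo1 rose from 0.755 ± 0.358 to 7.72 ± 5.75 TPM (2.50 ± 0.43, adjusted p = 0.017). Anxa7, Mk1 and Blvrb rose by 1.61, 1.37 and 1.20 log2, and AABR07008940.1, a name outside the naming rule chosen after its values were seen, rose by 1.73 ± 0.34 (adjusted p = 0.042).

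The metabolic genes Sds, Thrsp and Tat were lower. The serine dehydratase gene Sds fell from 119 ± 89.4 to 12.8 ± 5.46 TPM (-2.83 ± 0.54, adjusted p = 0.038). The lipogenic gene Thrsp fell from 72.6 ± 43.7 to 11.8 ± 2.69 TPM (-2.39 ± 0.35, adjusted p = 0.0041), and the tyrosine aminotransferase gene Tat from 98.2 ± 21.5 to 34.7 ± 9.33 TPM (-1.49 ± 0.27, adjusted p = 0.027). The stress gene Herpud1 fell by 1.81 ± 0.33 (adjusted p = 0.027), and it was chosen after its values were seen. Gsta3 (2.32, adjusted p = 0.064), Scd (-1.61, adjusted p = 0.659) and Cyp2b1 (2.12, adjusted p = 0.664) did not pass.

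**Figure D3:**
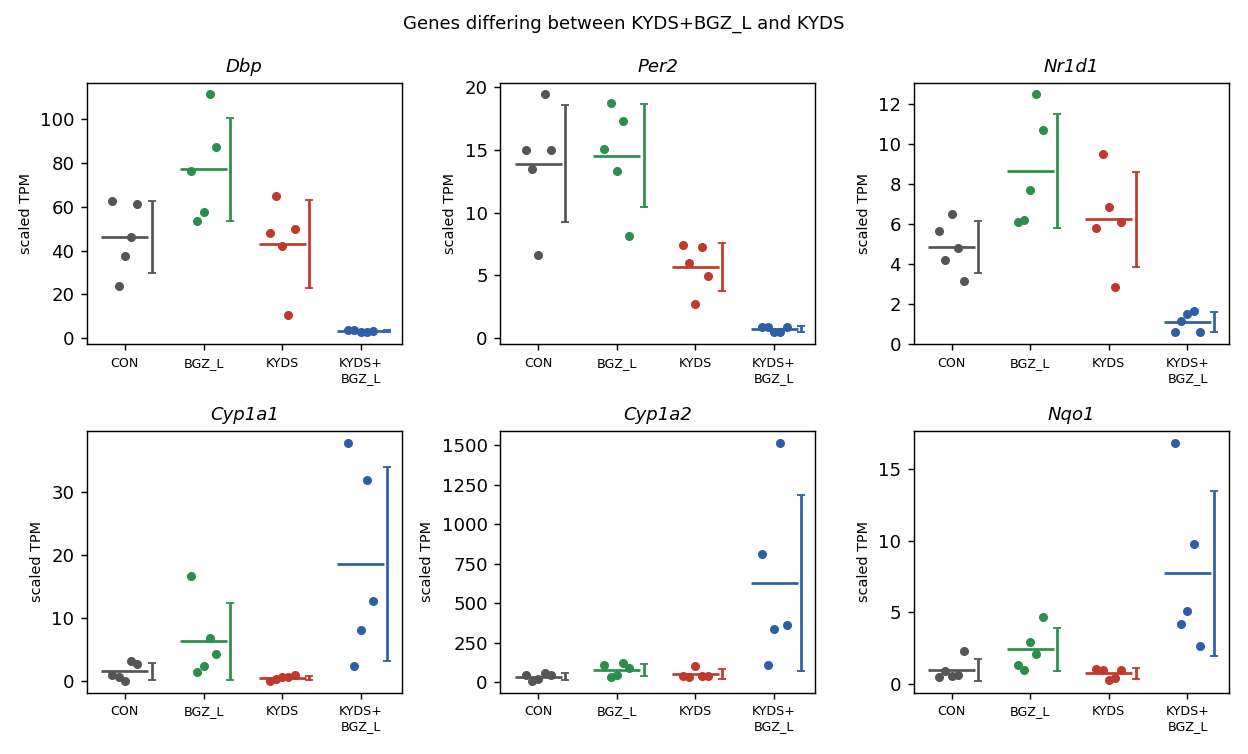
Scaled TPM per library (y axis, linear) of Dbp, Per2, Nr1d1, Cyp1a1, Cyp1a2 and Nqo1 in the 4 groups (points are libraries, line is the mean, bar is the SD, n = 5). Dbp, Per2 and Nr1d1 are lowest, and Cyp1a1, Cyp1a2 and Nqo1 have their highest means, in KYDS+BGZ_L.

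The glucocorticoid and metabolic genes named beforehand otherwise gave no call for BGZ_L on hydrocortisone. Tsc22d3 (-0.86), Per1 (-0.75), Cpt1a (-0.69), Fasn (-0.66), Cyp8b1 (-0.18), Nr3c1 (-0.14), Fkbp5 (-0.06) and Cyp2c11 (0.50) did not pass. Cyp7a1 (0.18), Igf1 (0.17) and Hsd11b1 (0.005) did not pass either, and all 3 turned negative without scaling and with nuclear TPM.

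As groups, 14 of 36 lists were called in KYDS+BGZ_L against KYDS, 7 higher and 7 lower. Of these 4 kept their call with an estimated correlation, and fry called 5. Of 17 clock genes 4 fell and 13 did not pass, with 2 higher (Arntl by 0.91 and Cry1 by 1.77, both chosen after their values were seen) and 7 lower when adjusted over the list alone (camera adjusted p = 5.5e-11, with adjusted p = 0.0016 with an estimated correlation). Of 5 aryl hydrocarbon receptor targets 3 rose and 2 did not pass, with the same 3 when adjusted over the list alone (adjusted p = 3.4e-10 and 0.0054 with an estimated correlation). Of 17 NRF2 targets 1 rose, Nqo1, and 16 did not pass, with 5 higher when adjusted over the list alone (adjusted p = 8.2e-10 and 0.0016 with an estimated correlation). Of 22 glucocorticoid receptor targets 2 fell, Tat and Sds, and 20 did not pass, with 1 higher and 5 lower when adjusted over the list alone (adjusted p = 3.1e-09 and 0.0016 with an estimated correlation).

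The other 10 called lists lost their call with an estimated correlation. Amino acid catabolism had 2 of 24 lower and 22 not passing (4 lower adjusted over the list alone, adjusted p = 2.6e-07 and 0.076 with an estimated correlation). Glycolysis and lipogenesis had 1 of 16 lower, Thrsp, and 15 not passing (adjusted p = 3.7e-07 and 0.076 with an estimated correlation). Thyroid hormone response also had only Thrsp lower, of 11 genes (adjusted p = 0.0034 and 0.061 with an estimated correlation). Nuclear-encoded oxidative phosphorylation was higher with 0 of 21 genes passing in limma (adjusted p = 9.0e-07 and 0.360 with an estimated correlation). CAR and PXR targets were higher with 0 of 19 genes passing (adjusted p = 8.9e-04 and 0.296 with an estimated correlation). Interferon response and gluconeogenesis were lower (adjusted p = 0.0014 and 0.0018, with adjusted p = 0.347 and 0.254 with an estimated correlation). Mitochondrially encoded transcripts were higher (adjusted p = 0.0028 and 0.634 with an estimated correlation), beside shares of TPM of 48.9% in KYDS+BGZ_L and 42.4% in KYDS (exact permutation p = 0.563, and 0.984 adjusted over 16 tests). Fatty acid oxidation and MHC class II genes were also higher (adjusted p = 0.0084 and 0.011, with adjusted p = 0.574 for each with an estimated correlation). Gluconeogenesis lost its call without KYDS 3 (adjusted p = 0.180) and MHC class II genes without KYDS+BGZ_L 3 (0.074). Mitochondrially encoded transcripts lost theirs without KYDS 3, KYDS+BGZ_L 2 or KYDS+BGZ_L 3 (0.276 at the most, where the mean of the list over that of other genes went from 0.39 to 0.076 without KYDS 3). Fatty acid oxidation lost it without KYDS 1, 4 or 5 or KYDS+BGZ_L 1 or 4 (0.195 at the most, where that mean went from 0.23 to 0.12 without KYDS+BGZ_L 1). The mitochondrially encoded list turned to -0.27 when the 10 most abundant genes were left out, and lost its call with no filter (adjusted p = 0.076). Leaving out the most abundant genes takes members out of this list, so that setting is no check of the whole list.

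In all, 15 genes passed between KYDS+BGZ_L and KYDS, 7 higher and 8 lower, each changed at least 2-fold, with 405 at an unadjusted p under 0.05. With nuclear TPM 3 were higher and 7 lower, with a median of all genes of -0.24 log2, and without scaling 0 were higher and 4 lower by limma, with a median of -0.36 log2. With 1 library left out, 6 genes passed without KYDS 2, 6 without KYDS+BGZ_L 1, 8 without KYDS+BGZ_L 3, 6 without KYDS+BGZ_L 4 and 8 without KYDS+BGZ_L 5. Dbp, Per2, Nr1d1, Thrsp and Anxa7 passed whichever library was left out. Without KYDS 2 the calls of Cyp1a2 (adjusted p = 0.133), Per3 (0.146), Sds (0.145), Tat (0.108), Herpud1 (0.133) and Blvrb (0.165) were lost. Without KYDS+BGZ_L 4 those of Cyp1a1 (0.091), Nqo1 (0.077) and Mk1 (0.077) were lost, and that of AABR07008940.1 was lost without KYDS+BGZ_L 1 (0.185). These values are the highest per gene, and the calls were lost in 2 (Nqo1) to 13 (Blvrb and AABR07008940.1) of 20 such fits.

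Whether the effect of BGZ_L differed with hydrocortisone was tested as an interaction. The clock genes Dbp and Nr1d1 were lower with BGZ_L in rats that received hydrocortisone, and gave no call for BGZ_L without it. Dbp gave an interaction of -4.14 ± 0.54 log2 (adjusted p = 0.0031) and Nr1d1 of -2.78 ± 0.42 (adjusted p = 0.011), with differences of 0.76 and 0.75 without hydrocortisone that did not pass. Per2 (-2.39 ± 0.42, adjusted p = 0.0505) and Sds (-3.65 ± 0.76, adjusted p = 0.214) did not pass. Dipk2a had the only other call, a positive interaction of 1.83 ± 0.31 (adjusted p = 0.034), and it was chosen after its values were seen. Its call was lost in 14 of 20 fits that left out 1 library, with an adjusted p of 0.112 at the most without KYDS 5.

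In all, 3 genes had an interaction, 1 positive and 2 negative, with 446 at an unadjusted p under 0.05. Without scaling 0 passed in limma, with a median of all genes of -0.40 log2. Leaving out CON 3, CON 4, BGZ_L 5 or KYDS 3 gave 5 genes each, and leaving out another library gave at least 2. Of 36 lists 13 were called, 7 positive and 6 negative. Glucocorticoid receptor targets (camera adjusted p = 6.9e-06) and clock genes (9.0e-06) were negative and kept their call, each with adjusted p = 0.034 with an estimated correlation. Aryl hydrocarbon receptor targets and NRF2 targets were positive (adjusted p = 1.3e-04 and 1.5e-04, with adjusted p = 0.114 and 0.065 with an estimated correlation). Interferon response and cholesterol synthesis went apart, the first negative (adjusted p = 2.2e-07 and 0.101 with an estimated correlation) and the second positive (adjusted p = 3.6e-06 and 0.516 with an estimated correlation). Amino acid catabolism and gluconeogenesis genes were negative (adjusted p = 4.6e-06 and 1.9e-04, with adjusted p = 0.131 and 0.143 with an estimated correlation). The other 5 calls, CAR and PXR targets, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, macrophage genes and cholangiocyte genes, had an adjusted p of 0.516 to 0.741 with an estimated correlation, and the nuclear to mitochondrial ratio as a covariate ended 3 of them, mitochondrially encoded transcripts (0.283, which turned to -0.077), macrophage genes (0.065) and cholangiocyte genes (0.065). Of 20 fits without 1 library, 9 ended the call of CAR and PXR targets (adjusted p = 0.259 at the most, without CON 4), 8 that of oxidative phosphorylation (0.216, without BGZ_L 1), 11 that of cholangiocyte genes (0.195, without CON 4), 3 that of macrophage genes (0.458, without BGZ_L 2, where the mean against other genes went from -0.77 to -0.21) and 1 that of mitochondrially encoded transcripts (0.087, without CON 2). Without CON 5 the mean of cholesterol synthesis genes over that of other genes went from 0.85 to 0.47 (adjusted p = 0.0055). The nuclear to mitochondrial ratio is computed from the mitochondrially encoded transcripts, so as a covariate it is no separate check of that list.

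BGZ_L against CON asks what BGZ_L did on its own. No gene passed. The ammonium transporter gene Rhbg came closest, from 3.66 ± 2.65 TPM in CON to 16.8 ± 6.06 TPM in BGZ_L (2.23 ± 0.38 log2, adjusted p = 0.105, n = 5 per group), with all 5 BGZ_L libraries above all 5 CON libraries. Cbx5 was at -0.70 (adjusted p = 0.523). Iqch and Pgap2 were at 1.23 and 1.14 (adjusted p = 0.358 for each). Cyp8b1 was at 2.07 (adjusted p = 0.393), Cyp1a1 at 1.60 (adjusted p = 0.784) and Cyp1a2 at 1.17 (adjusted p = 0.826).

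The lists of cholesterol synthesis and of glycolysis and lipogenesis lay lower with BGZ_L alone. In cholesterol synthesis, 0 of 23 genes passed in limma and 1 fell when adjusted over the list alone (camera adjusted p = 1.2e-07, with adjusted p = 0.664 with an estimated correlation). Mvk was at -0.71 (adjusted p = 0.397) and Idi1 at -1.72 (adjusted p = 0.761). The mean of the list against that of other genes went from -0.81 to -0.43 without CON 5 (adjusted p = 0.0026) and to -0.54 without CON 4 (adjusted p = 3.6e-04), and Idi1 was at 25.5 and 11.2 TPM in these libraries, with 2.85 at most in the other CON libraries. Glycolysis and lipogenesis genes were lower with 0 of 16 passing and 2 lower when adjusted over the list alone (adjusted p = 1.8e-04 and 0.664 with an estimated correlation), with Fasn at -1.63 (adjusted p = 0.442). Macrophage genes were higher (adjusted p = 5.1e-04 and 0.673 with an estimated correlation), with Marco at 1.64 (adjusted p = 0.559) and Cd5l at 1.44 (adjusted p = 0.784). Leaving out BGZ_L 2 ended that call (adjusted p = 0.367) and the call of interferon response genes (adjusted p = 0.0545).

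Interferon response genes were higher (adjusted p = 5.2e-04 and 0.664 with an estimated correlation), with Psmb9 at 0.98 (adjusted p = 0.523) and Usp18 at 0.61 (adjusted p = 0.784). Cholangiocyte genes were lower (adjusted p = 0.010 and 0.664 with an estimated correlation), with Sox9 at -0.80 (adjusted p = 0.784) and Spp1 at -1.17 (adjusted p = 0.827). Their call was lost in 5 of 20 fits without 1 library, with the highest adjusted p of 0.090 without CON 4, and with a stricter filter (adjusted p = 0.062). Erythroid genes were higher (adjusted p = 0.017 and 0.664 with an estimated correlation), with Alas2 at 0.98 (adjusted p = 0.813) and Ahsp at 0.50 (adjusted p = 0.827). Their call was lost in 3 of 20 fits, with the highest adjusted p of 0.212 without CON 3, and with no filter (adjusted p = 0.096), nuclear TPM (0.060) or without CON 2 and BGZ_L 3 (0.154). None of these 6 lists was called by fry. Glucocorticoid receptor targets had a median of -0.03, a mean of 0.02 and a test that pointed higher (adjusted p = 0.847).

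Of the remaining genes named beforehand, Hsd11b1 was at -0.84, Cyp7a1 at -0.96, Cyp2c11 at -0.52, Tat at -0.24, Nr3c1 at -0.14, Cpt1a at -0.12 and Fkbp5 at -0.05, and none passed. Cyp2b1 (0.13), Per1 (0.10) and Igf1 (0.04) did not pass and turned negative with nuclear TPM, and Tsc22d3 (-0.02) did not pass and turned positive without scaling. The count of 0 genes in BGZ_L against CON came from limma, with 714 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.105. Median-ratio scaling, nuclear TPM and no scaling also gave 0, and nuclear TPM moved the median of all genes by -0.28 log2. Without single libraries there was 1 gene without CON 3, 3 without CON 5, 2 without BGZ_L 1 and 1 without BGZ_L 5. The median SE of 0.33 log2 limits what this comparison can call. It was the same in KYDS against CON, where 744 genes passed, because the fit shares its estimate of spread over all groups. That equality does not show equal precision. The median gene SD was 0.551 log2 in CON, 0.544 in BGZ_L, 0.462 in KYDS and 0.377 in KYDS+BGZ_L.

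KYDS+BGZ_L against CON sets both treatments together against the vehicle. Per2 fell by 3.53 ± 0.30 log2 (adjusted p = 2.7e-06) and Dbp changed by -3.60 ± 0.38 (adjusted p = 2.4e-05). Cyp1a2 rose by 3.75 ± 0.58 (adjusted p = 9.6e-04), Cyp1a1 by 2.99 ± 0.67 (adjusted p = 0.011), Nqo1 by 2.31 ± 0.43 (adjusted p = 0.0038) and Cyp2b1 by 3.89 ± 0.68 (adjusted p = 0.0026). Gckr rose by 3.71 ± 0.40 (adjusted p = 2.4e-05) and Ces2c by 5.00 ± 0.58 (adjusted p = 4.2e-05). These 8 genes were singled out in this comparison after their values were seen.

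Of 36 lists 14 were called in KYDS+BGZ_L against CON, 11 higher and 3 lower, with 1 kept with an estimated correlation and 12 called by fry. The list kept was the clock, with 1 gene higher, 9 lower and 7 not passing of 17, and 2 higher and 12 lower when adjusted over the list alone (camera adjusted p = 5.3e-06, with adjusted p = 0.035 with an estimated correlation). Of 5 aryl hydrocarbon receptor targets 4 rose and 1 did not pass, also when adjusted over the list alone (adjusted p = 2.1e-04 and 0.210 with an estimated correlation). Of 28 fatty acid oxidation genes 9 rose and 19 did not pass, with 15 higher and 1 lower when adjusted over the list alone (adjusted p = 8.7e-05 and 0.441 with an estimated correlation). Of 22 glucocorticoid receptor targets 1 rose, 7 fell and 14 did not pass, with 2 higher and 9 lower when adjusted over the list alone (adjusted p = 0.011 and 0.313 with an estimated correlation). In all, 1364 genes passed, 687 higher and 677 lower, with 3407 at an unadjusted p under 0.05. No scaling gave 1565 higher and 88 lower with a median of all genes of 0.64 log2, and nuclear TPM gave 126 and 240 with a median of -0.23 log2. The count was 681 genes without CON 2, 408 without KYDS+BGZ_L 1 and 385 without KYDS+BGZ_L 4.

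Whether BGZ_L turned back hydrocortisone changes was asked of genes called in both KYDS against CON and KYDS+BGZ_L against KYDS. Herpud1 rose with hydrocortisone (1.10 ± 0.33 log2, adjusted p = 0.0497) and fell with BGZ_L added (-1.81 ± 0.33, adjusted p = 0.027). AABR07008940.1 fell (-1.95 ± 0.34, adjusted p = 0.0030) and then rose (1.73 ± 0.34, adjusted p = 0.042). Per2 and Mk1 were called in both comparisons in the same direction, Per2 lower (-1.22 and -2.31) and Mk1 higher (1.23 and 1.37). These 4 genes were chosen after their values were seen, and Per2 turned to 0.05 without scaling in the first comparison.

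Against the 744 genes called between KYDS and CON, the 2 reversed genes compare with 0.260 and 0.211 expected in each direction for independent gene sets. The comparisons share the KYDS libraries with opposite sign, which alone favours opposite signs. Data simulated for unchanged groups with the same sharing gave a mean of 0.01 reversed genes (0 to 1 in 100 draws). With no group changed hardly any gene is called, so that count is near 0 by construction and is no baseline here. Dividing the KYDS libraries between the comparisons gave 0 as a median of 20 splits, with fewer KYDS libraries in each comparison. Among the 744 genes 56.0% had opposite signs in the second comparison, within the range of the splits (median 48.8%, 12.6 to 67.9). That share also lies within the simulated range (mean 86.9%, 40.6 to 100), but the simulated range concerns genes ranked first in data without any change. Across all genes, which are not independent replicates, the correlation of the fold changes was -0.10, within the simulated range (mean -0.50, from -0.83 to 0.035) and that with the KYDS libraries divided (median 0.05, from -0.19 to 0.49). Leaving out 1 library gave between 0 and 4 reversed genes, 4 without CON 4, and the count was beyond 1.5 times in 17 of 20 such fits. The Herpud1 rise with hydrocortisone was lost in 18 of 20 fits, with an adjusted p of 0.125 at the most without CON 2.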

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

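The tests of gene length (as gene span), time of day and the aryl hydrocarbon receptor score were chosen only after the results they concern were seen, and the comparison of KYDS+BGZ_L with BGZ_L was added after the data were seen.

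In the first pattern, 744 genes changed between KYDS and CON, in libraries whose mitochondrial share also differs. With the log2 nuclear to mitochondrial ratio as a covariate, 61.9% of their median signed change was left (55.5 to 66.4 when single libraries were left out). All 744 kept their sign. These genes were picked and signed by their change in the same libraries, which favours a remainder of the same sign. The test therefore does not decide whether that ratio is the whole source. The median change went from 1.41 ± 0.35 to 0.87 ± 0.39 log2 (median SE), and all but 21 of the calls ended, since the change shrank and its error grew. A trend on gene span left 97.3% of the median change of the 665 called genes with a known span (89.4%). Its range of 94.5 to 99.5 is a 95% bootstrap over genes, which are not independent replicates. The median span was 22184 bp in genes called higher, 49680 bp in genes called lower and 24184 bp in all. Transcript length was not tested. A larger share of hepatocyte RNA cannot be told apart from hydrocortisone here. Of 9 marker lists of other cell types 4 had medians above 0 (-0.65 to 0.60) beside 1.30 for hepatocyte genes. Lists that move both ways decide nothing. With the covariate the hepatocyte median was 0.067, erythroid genes were called higher (median 1.13, adjusted p = 0.0014) and MHC class II genes lower (median -0.83, adjusted p = 0.018), and neither of these lists was called without it (adjusted p = 0.326 and 0.566). Of 100 splits of these 10 libraries only the real one called as many genes (744, with 22 as the highest other), so chance can be excluded, and a response to hydrocortisone stays open beside a difference in RNA composition.

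The second pattern is the fall of 4 clock genes in KYDS+BGZ_L against KYDS. These 4 were picked by their calls in this comparison. With the nuclear to mitochondrial ratio as a covariate 98.3% of their median change was left (96.8 to 99.8), from 2.38 ± 0.34 to 2.33 ± 0.32 log2. Mean mitochondrial shares were close, 42.4% in KYDS and 48.9% in KYDS+BGZ_L (exact permutation p = 0.563), so the covariate could take off little. The value leaves little room for a linear effect of that ratio, but decides no more on the source of this fall. Livers taken at another time of day may explain it and cannot be told apart from BGZ_L, since the 4 tested genes that peak at the opposite time had a median of 0.49 log2 (0.41 to 0.72), with Arntl at 0.91 and Cry1 at 1.77 but Clock at 0.07 and Nfil3 at 0.06, and the labels used here give no times. An effect of BGZ_L together with hydrocortisone, which the interactions of Dbp and Nr1d1 name, stays open as well. Of 100 splits of the KYDS and KYDS+BGZ_L libraries 3, the real one included, called as many genes (15, with 1281 as the highest other). That share lies under 0.05, but another split called far more genes than the real one, so chance is not excluded for the count. A split with that many genes points to a structure of the samples other than their groups.

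The third pattern is the rise of aryl hydrocarbon receptor targets with BGZ_L. The mean log2 score of 5 members was 2.37 ± 0.727 in CON, 2.93 ± 0.648 in BGZ_L, 2.65 ± 0.114 in KYDS and 4.69 ± 0.916 in KYDS+BGZ_L (SD, n = 5). With hydrocortisone it differed by 2.04 (exact permutation p = 0.00794, the smallest possible, and 0.0238 adjusted over 3 tests, with 5 of 5 libraries above all KYDS libraries), and without it by 0.56 (exact permutation p = 0.246, also 0.246 adjusted, with 2 of 5 above all CON libraries). The second p alone does not show that the score did not differ, but the interaction of 1.48 (permutation p = 0.0192, adjusted 0.0288) argues against the same rise without hydrocortisone. As a gene list, the interaction was called by camera at the preset correlation (adjusted p = 1.3e-04), but not with an estimated correlation (0.114) or by fry (0.130). With the nuclear to mitochondrial ratio as a covariate 109% of the difference with hydrocortisone was left (101 to 121 when single libraries were left out), from 2.04 ± 0.42 to 2.22 ± 0.31 log2. Mean mitochondrial shares were close here too (42.4% in KYDS and 48.9% in KYDS+BGZ_L), so the covariate could take off little. The value leaves little room for a linear effect of that ratio, but decides no more on the source of this rise. No other technical explanation was tested for this score, and an effect of BGZ_L that depends on hydrocortisone stays open.

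For the other comparisons, BGZ_L against CON called 0 genes in limma, with 714 at an unadjusted p under 0.05. A count of 0 is met by 100 of 100 splits by construction and says nothing about chance, but the highest other split called 1875 genes, which points to a structure of those samples other than treatment. For KYDS+BGZ_L against CON 1 of 100 splits, the real one, called as many (1364, with 1 as the highest other). For KYDS+BGZ_L against BGZ_L it was also 1 of 100 (2059, with 5 as the highest other). Chance is unlikely for both but not excluded, since splits that mix different groups call few genes. For the interaction 3 of 100 splits, the real one included, called as many (3, with 1245 as the highest other). That share lies under 0.05, but another split called far more genes, so chance is not excluded for the count. The highest split again points to a structure of the samples.

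The interaction differed from 0 for Dbp (-4.14), Nr1d1 (-2.78) and Dipk2a (1.83), so the difference between groups with and without BGZ_L was not the same with and without hydrocortisone. For Dbp and Nr1d1 the time of day stays open as described with the clock genes. The call of Dipk2a was lost in 14 of 20 fits that left out 1 library (adjusted p = 0.112 at the most), and it has no further test.

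Single libraries stood apart from the other 4 of their group in 15 of 268 tests, where chance gives about 1 in 20, or 13.4. The measure is the gap to the nearest library over the range of the group, with a critical value of 0.71. Among the genes of KYDS against CON these were CON 3 for Cyp2c11 (0.889) and Orm1 (0.807), CON 4 for G6pc (0.899), KYDS 3 for Cyp1a2 (0.843) and KYDS 4 for Dnah7 (0.981). KYDS 4 also stood apart for Dbp (0.755). BGZ_L 1 stood apart for G6pc (0.732), Per1 (0.728) and the share of ribosomal RNA (0.871), which was 20.6% there. BGZ_L 3 stood apart for Sds (0.731), BGZ_L 4 for Spp1 (0.873) and BGZ_L 5 for Tuba1c (0.981). KYDS+BGZ_L 3 stood apart for Atl1 (0.737) and Myh15 (0.840), and KYDS+BGZ_L 4 for Cpt1a (0.830).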

How the results depend on the processing

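The settings with another added constant, no scaling, nuclear TPM, array weights, the mitochondrial covariate or without CON 2 and BGZ_L 3, and all of KYDS+BGZ_L against BGZ_L, were chosen only after the data were seen. The planned second count tool was not run, since the values were read as TPM, and the setting with only the groups of a comparison gives no value for the interaction, which uses all 4. The separation of libraries on PC1 held with the 500 most variable genes (permutation p = 2e-05). Ces2c, Gckr and Tymp in KYDS against CON, and Dbp and Per2 in KYDS+BGZ_L against KYDS, passed in all 33 of their alternatives. TPM keeps no depth, so what depth limits cannot be given.

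KYDS against CON (744 genes) gave 367 with no filter, 257 with only its groups, 5932 without scaling, 129 with nuclear TPM, 23 with the covariate, 257 without CON 2 and BGZ_L 3, and 226 to 1075 without 1 library. KYDS+BGZ_L against KYDS (15) gave 3 with only its groups, 4 without scaling, 89 with array weights and 6 to 19 without 1 library. BGZ_L against CON (0 in limma, 714 at an unadjusted p under 0.05) gave 1 with the covariate, 1 without CON 2 and BGZ_L 3, and 0 to 3 without 1 library. KYDS+BGZ_L against CON (1364) gave 877 with no filter, 366 with nuclear TPM, 89 with the covariate, 765 without CON 2 and BGZ_L 3, and 385 to 1611 without 1 library. The interaction (3) gave 0 in limma without scaling, 1 with nuclear TPM, 9 with array weights, 1 without CON 2 and BGZ_L 3, and 2 to 5 without 1 library. KYDS+BGZ_L against BGZ_L (2059) gave 900 with nuclear TPM, 669 with the covariate, 1362 without CON 2 and BGZ_L 3, and 1101 to 2517 without 1 library. The count of reversed genes (2) was 0 with median-ratio scaling, only the groups or the covariate, and 1 with no filter, the replicate block, the 10 most abundant genes left out, a constant of 0.1, nuclear TPM or without CON 2 and BGZ_L 3. It was 21 with array weights and 0 to 4 without 1 library. The replicate block, which pairs rats by number, gave 557, 15, 0, 1160, 3 and 1889 genes in the order above. Using only the groups leaves 8 residual degrees of freedom, and the cause of the other changes was not tested.

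None of the 27 results whose sign turned in some setting passed the threshold there, and for each the cause was not tested. Without scaling, KYDS against CON gave Cyp7a1 0.27, Fasn 0.85, Fkbp5 0.29, Per1 0.30, Tsc22d3 0.60, Nfkbia 0.63 and Per2 0.046. KYDS+BGZ_L against KYDS gave Cyp7a1 -0.21, Hsd11b1 -0.43 and Igf1 -0.27, and BGZ_L against CON gave Tsc22d3 0.050. With nuclear TPM, KYDS+BGZ_L against KYDS gave Cyp7a1 -0.054, Hsd11b1 -0.25 and Igf1 -0.084, and BGZ_L against CON gave Cyp2b1 -0.18, Igf1 -0.29 and Per1 -0.19. With the covariate, KYDS against CON gave Cyp1a2 -0.94, Cyp2c11 -0.25, Nr3c1 -0.063, Tat -0.088 and acute phase proteins -0.032. KYDS+BGZ_L against KYDS gave Cyp8b1 0.071, BGZ_L against CON gave Cyp2b1 -0.17, Igf1 -0.14 and Per1 -1.8e-04, KYDS+BGZ_L against BGZ_L gave Cyp8b1 -0.26, and the interaction gave mitochondrially encoded transcripts -0.077. With array weights Fasn was 0.10 in KYDS against CON, and Cyp7a1 was -0.046 and Fkbp5 0.024 in KYDS+BGZ_L against KYDS. A constant of 0.1 gave Fasn 1.8e-04 in KYDS against CON, and only the groups gave Tsc22d3 0.0038 in BGZ_L against CON. Without CON 2 and BGZ_L 3, Cpt1a was 0.032 and Igf1 -0.19 in BGZ_L against CON. Without the 10 most abundant genes, which include members of that list, mitochondrially encoded transcripts were -0.27 in KYDS+BGZ_L against KYDS.

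Without 1 library, KYDS against CON gave Fasn -0.46 to 0.20. KYDS+BGZ_L against KYDS gave Cyp7a1 -0.095 to 0.36, Cyp8b1 -0.55 to 0.12, Fkbp5 -0.13 to 0.092, Hsd11b1 -0.13 to 0.18, Igf1 -0.26 to 0.41 and Nr3c1 -0.34 to 0.0093. BGZ_L against CON gave Cpt1a -0.42 to 0.053, Cyp2b1 -0.34 to 0.65, Fkbp5 -0.18 to 0.081, Igf1 -0.13 to 0.15, Per1 -0.21 to 0.30 and Tsc22d3 -0.18 to 0.10. Among the other settings of named genes in KYDS against CON, 1532 kept sign and side of the threshold, 382 lost the call and 5 gained one. In KYDS+BGZ_L against KYDS these counts were 871, 122 and 6, and in BGZ_L against CON 985 kept both and 1 gained a call. List calls were kept in 349 settings and lost in 34 for KYDS against CON, and in 458 and 30 for KYDS+BGZ_L against KYDS. The covariate also gave list calls absent without it, beside those of KYDS against CON. Hepatocyte genes were higher in KYDS+BGZ_L against KYDS (adjusted p = 0.028), and acute phase (0.0033) and hepatocyte genes (0.046) lower in BGZ_L against CON. Male-biased (0.022), acute phase (0.0011), sphingolipid (0.043) and hepatocyte genes (0.0022) had a positive interaction.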

Other observations

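All genes of this part were chosen after their values were seen, and KYDS+BGZ_L against BGZ_L was itself added after the data were seen.

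Several genes of membrane lipid metabolism were higher with hydrocortisone in both comparisons that differ by it. With the nuclear to mitochondrial ratio as a covariate 23 genes passed in KYDS against CON, and no gene of this part was among them. The ceramide synthase Cers2 rose by 1.69 ± 0.36 log2 in KYDS against CON (adjusted p = 0.014) and by 1.73 ± 0.36 in KYDS+BGZ_L against BGZ_L (adjusted p = 0.0047). The sphingomyelinase Smpd1 rose by 1.503 ± 0.33 (adjusted p = 0.015) and 1.49 ± 0.33 (adjusted p = 0.0060). The choline kinase Chka rose by 1.84 ± 0.41 (adjusted p = 0.017) and 2.84 ± 0.41 (adjusted p = 4.8e-04). Agpat2 rose by 1.11 ± 0.29 in each (adjusted p = 0.031 and 0.013), a call that was lost in KYDS against CON without KYDS 3 (adjusted p = 0.088). In KYDS+BGZ_L against BGZ_L, Pemt, which makes phosphatidylcholine, rose by 2.74 ± 0.60 (adjusted p = 0.0056) and Lpcat1 fell by 1.89 (adjusted p = 0.0041). Of 18 sphingolipid genes 2 rose and 16 did not pass in KYDS against CON (4 rose adjusted over the list alone, camera adjusted p = 0.245), and 5 rose, 1 fell and 12 did not pass in KYDS+BGZ_L against BGZ_L (6 rose and 1 fell adjusted over the list alone, adjusted p = 0.025, with adjusted p = 0.412 with an estimated correlation). Of 22 glycerophospholipid genes 4 rose in each, with 0 and 1 lower by limma, and neither list was called (camera adjusted p = 0.193 and 0.533), although the covariate gave a call in KYDS against CON (adjusted p = 0.041).

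Genes of matrix and of the steroid pathway gave single changes. The fibronectin gene Fn1 rose by 2.28 ± 0.51 log2 in KYDS against CON (adjusted p = 0.017) and by 2.74 ± 0.51 in KYDS+BGZ_L against BGZ_L (adjusted p = 0.0025), and the stellate cell gene Pdgfrb by 1.98 ± 0.33 (adjusted p = 0.0023) and 2.20 ± 0.33 (adjusted p = 5.8e-04). Each was the only member of its list to pass, of 14 matrix genes and 9 stellate cell genes, and the lists pointed lower without a call (camera adjusted p = 0.566 and 0.355 in KYDS against CON). The steroid hydroxylase gene Cyp17a1 rose by 1.97 ± 0.46 in KYDS against CON (adjusted p = 0.021), a call that was lost without CON 3 and without KYDS 3 (adjusted p = 0.053 at the most).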
